A study of Mus musculus with 15 samples.

How the data were processed

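RNA of ileal organoids (15 libraries, in 5 groups of 3) was sequenced by the authors after poly-A selection and TruSeq library preparation. Per the labels the organoids were split on day 10 and treated on day 14 at passage 2, and RNA integrity numbers were above 8. The submitters' notes name bcl2fastq 2.17, STAR 2.5.2b and featureCounts 1.5.0-p3 with genome build mm10 (GRCm38). The deposited files hold raw read counts per gene symbol, 1 column per library, with no normalization. Annotation, strand setting and treatment of multimapping reads were not given. Each file holds 23420 symbols, of which 21777 have coordinates in GENCODE vM21, and totals ran from 11245807 to 28989526 counts.

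Genes were kept by filterByExpr (13159), scaled by TMM and tested by edgeR quasi-likelihood F tests (robust, two-sided) on 1 model of 5 group means with 10 residual degrees of freedom. Benjamini-Hochberg adjusted p under 0.05 over all tested genes in a contrast counts as a change. The contrasts were each pool minus vehicle, the mean of the 4 pools minus vehicle, H90 minus H10, M90 minus M10, M10 minus H10, M90 minus H90, and the interaction of share and species model. The common dispersion was 0.00776, a biological coefficient of variation of 0.0881. Standard errors and 95% intervals come from the quasi-likelihood F and so hold the spread between these libraries, while the floor of 3 counts covers counting error only. CPM values use TMM-scaled totals, except that the levels of Mup20, Col1a1, Alb, Rn45s and the liver list per library use plain totals. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, python 3.11.15 and matplotlib 3.10.9 were used.

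Gene lists (32, with 743 genes, 726 of them matched) were written before the data were examined, and 29 with at least 5 tested members were tested by camera on log2 CPM (prior count 3, preset correlation 0.01) and adjusted over the lists of each contrast. Camera with an estimated correlation and fry were alternatives, and fry asks only whether a list's own members change. No symbol of the mitochondrial list was in the files. MHC class II and mesenchymal markers had 4 tested members each, too few for the test, and on the mean of the pools 0 and 2 of these passed.

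Named genes were fixed by a rule made before the data were examined. It takes 8 genes everywhere, called bile acid genes below, though Slc30a10 among them was named as a subject of the study. It also takes the 10 largest changes each way for the mean of the pools and the 4 contrasts between pools, 5 each way for single pools and the interaction, and up to 4 members with the smallest adjusted p of each list described. Ranked genes needed adjusted p under 0.05, a mean of at least 2 CPM over the 15 libraries and, except for the interaction, CPM ranges of the sides that did not overlap, which chance gives 10% of the time for 3 against 3. Predicted genes without a name were passed over, at most 1 in each direction of a contrast, and a few genes the rule picks are not reported here. S100g in M90 minus M10, Alb, Rn45s, the levels of Mup20 and Col1a1 per library, and Per1 fall outside the rule and were chosen after their values were seen.

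Alternatives fixed beforehand were RLE, upper-quartile and library size scaling, other filters, non-robust shrinkage, limma-voom, DESeq2, fits of the contrast's groups alone, a block for replicate letters, and leaving out each library. Letters were not used as pairs in the model: correlations of residual profiles between libraries of a shared letter ran from -0.0237 to 0.0829 (median 0.00499) and of other letters from -0.0579 to 0.05. Still, 11 of 15 libraries correlated best with their own letter and the 3 pairs of H10 and H90 were all positive (0.0829, 0.045 and 0.0294), so some pairing is not ruled out. Chosen after seeing the data were a term for library set (the 2 sets told apart by Mup20 above or below 10 CPM), fits within 1 set, leaving out the liver list, and voom with weights per group. The pipeline was tested on simulated data with 200 changed genes of 13159, where H10 minus vehicle recovered 63.2% of 1.5-fold and 88.9% of 4-fold changes. False calls were 4.25 to 6.05% of calls with a spread shared by all groups, and with each group's own spread 15.2% for M10 minus vehicle and M90 minus M10, 13.5% for M10 minus H10, 11.3% for the interaction, 10.7% for H90 minus vehicle and at most 7.79% elsewhere. These shares depend on the number of changed genes, here 200, and do not carry over to the real contrasts, where many more genes were called.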

Results

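The series holds 15 RNA sequencing libraries from primary ileal organoids, epithelial cultures grown from the crypts of C57BL/6 mouse ileum. Organoids were kept for 24 h in medium with 0.2% albumin and either vehicle or 1 of 4 bile acid pools, and each of the 5 groups had 3 libraries (a, b and c). The pools were modelled on human (H10, H90) or mouse (M10, M90) bile acids, with 10% or 90% of the bile acids 12α-hydroxylated, that is, carrying a hydroxyl group at carbon 12 of the sterol ring. Composition and dose of the pools were not given, so differences between pools are differences between whole mixtures. Nothing in the labels says whether the 3 libraries of a group came from separate animals or cultures. Total counts per library were 15712320, 27136476 and 21530317 for vehicle a to c, 18722586, 19378268 and 25845919 for H10 and 24084774, 17451139 and 11245807 for H90. They were 28989526, 26085428 and 21585731 for M10 and 20589358, 23556439 and 23756333 for M90. On the first principal component, with 55.2% of the variance, vehicle lay at -63.9 to -58.9, H90 at -40.8 to -33.6, H10 at 11.4 to 14.1, M90 at 16.0 to 20.3 and M10 at 66.2 to 68.5.

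Some transcripts split the libraries in a way the groups do not. Mup20, a major urinary protein made in liver, had 23.0 to 35.9 CPM (counts per 10⁶ counts of the library) in 7 libraries (vehicle, H10 and H90 a, set 1) and 0.356 to 0.583 CPM in the other 8 (H90 b and c, M10 and M90, set 2). Col1a1, a fibroblast collagen, ran the other way, with 0 to 0.107 CPM in set 1 and 3.74 to 8.63 CPM in set 2. Alb, serum albumin, had 93.5 to 137 CPM in set 1 and 32.5 to 65.7 CPM in set 2. The 29 genes of a liver list together took 0.0419 to 0.0622% of counts in set 1 and 0.0127 to 0.0217% in set 2. That list was written after the data were seen. The labels name no batch, vehicle and H10 lie in set 1, M10 and M90 lie in set 2, and H90 alone has libraries of both. Separately, the H90 and M10 libraries held 213 to 297 genes at exactly 1 count against 450 to 603 in the other 9 libraries. H90 a also had 14143 CPM of Rn45s, ribosomal precursor RNA, against 1739 to 3215 CPM in the other 14 libraries.

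**Figure D1:**
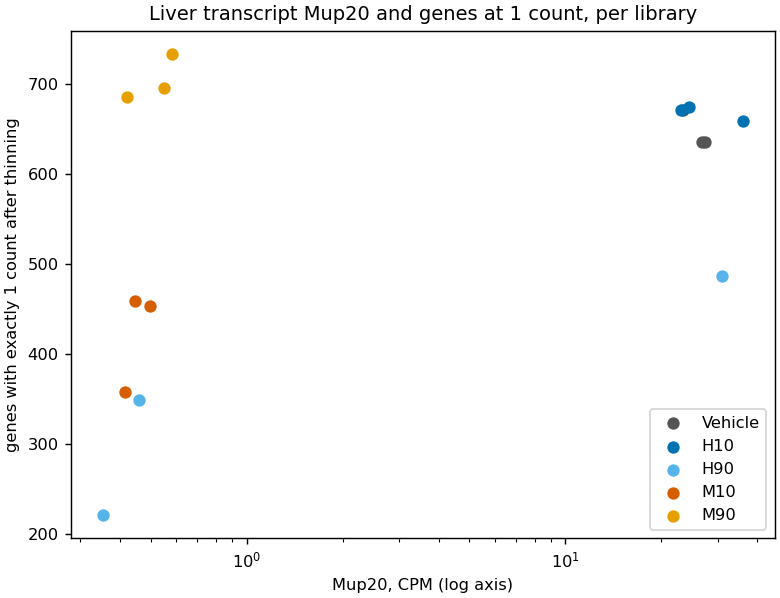
Mup20 in CPM (log axis) against the number of genes at exactly 1 count after thinning to equal depth, 1 point per library, coloured by group. H90 a lies with the vehicle and H10 libraries at 23.0 to 35.9 CPM, and the 6 H90 and M10 libraries hold 221 to 487 such genes against 635 to 733 in the other 9.

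The comparison of the mean of the 4 pools with vehicle asks what bile acids as a class did to ileal epithelium. Of 8 genes named beforehand, Slc30a10 among them as a subject of the study, 7 rose. Fabp6, the ileal cytosolic bile acid binding protein, went from 56.7 ± 9.23 CPM (mean ± SD, n = 3) in vehicle to 7335 ± 381 in H10, 5018 ± 489 in H90, 7316 ± 332 in M10 and 10590 ± 124 in M90, 129.6-fold on the mean of the pools. Fgf15, the hormone by which ileum restrains hepatic bile acid synthesis, rose 49.9-fold from 16.8 ± 2.22 CPM, and Nr0b2, the repressor SHP, rose 52.8-fold from 0.285 ± 0.326 CPM. The 2 subunits of the basolateral bile acid exporter, Slc51a and Slc51b, rose 6.42-fold from 184 ± 4.56 CPM and 10.7-fold from 52.8 ± 2.45 CPM. Slc30a10, a manganese exporter, rose 4.85-fold from 15.5 ± 2.55 CPM, and Nr1h4, the bile acid receptor FXR itself, rose 1.33-fold from 121 ± 3.82 CPM. Slc10a2, the apical bile acid importer, did not pass on the mean of the pools (log2 0.10, 95% interval -0.14 to 0.33, adjusted p = 0.469 by edgeR), and its sign turns with library size as the only scaling.

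Each of the other 7 genes passed the edgeR quasi-likelihood test on the mean of the pools, with a log2 change of 7.02 (SE 0.127, adjusted p = 3.19e-13) for Fabp6. It was 5.72 (SE 0.348, adjusted p = 1.36e-13) for Nr0b2 and 5.64 (SE 0.0869, adjusted p = 2.89e-20) for Fgf15. For the exporter subunits it was 3.42 (SE 0.0508, adjusted p = 2.89e-35) for Slc51b and 2.68 (SE 0.0431, adjusted p = 2.12e-34) for Slc51a. For Slc30a10 it was 2.28 (SE 0.116, adjusted p = 7.23e-12) and for Nr1h4 0.41 (SE 0.0428, adjusted p = 1.27e-10). All 12 treated libraries lay above all 3 vehicle libraries for each of Fabp6, Nr0b2, Fgf15, Slc51a, Slc51b and Slc30a10. On GRCm38 these protein-coding genes lie at chromosome 1, 185454848 to 185468762 (Slc30a10), chromosome 7, 144896531 to 144900953 (Fgf15), chromosome 4, 133553376 to 133556536 (Nr0b2) and chromosome 16, 32474504 to 32487879 (Slc51a). The others lie at chromosome 9, 65412714 to 65422955 (Slc51b), chromosome 11, 43596049 to 43601540 (Fabp6), chromosome 8, 5083219 to 5105351 (Slc10a2) and chromosome 10, 89454234 to 89533585 (Nr1h4). Slc30a10 is known as a subject of the study these libraries were made for, so its change here is not independent evidence.

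**Figure D2:**
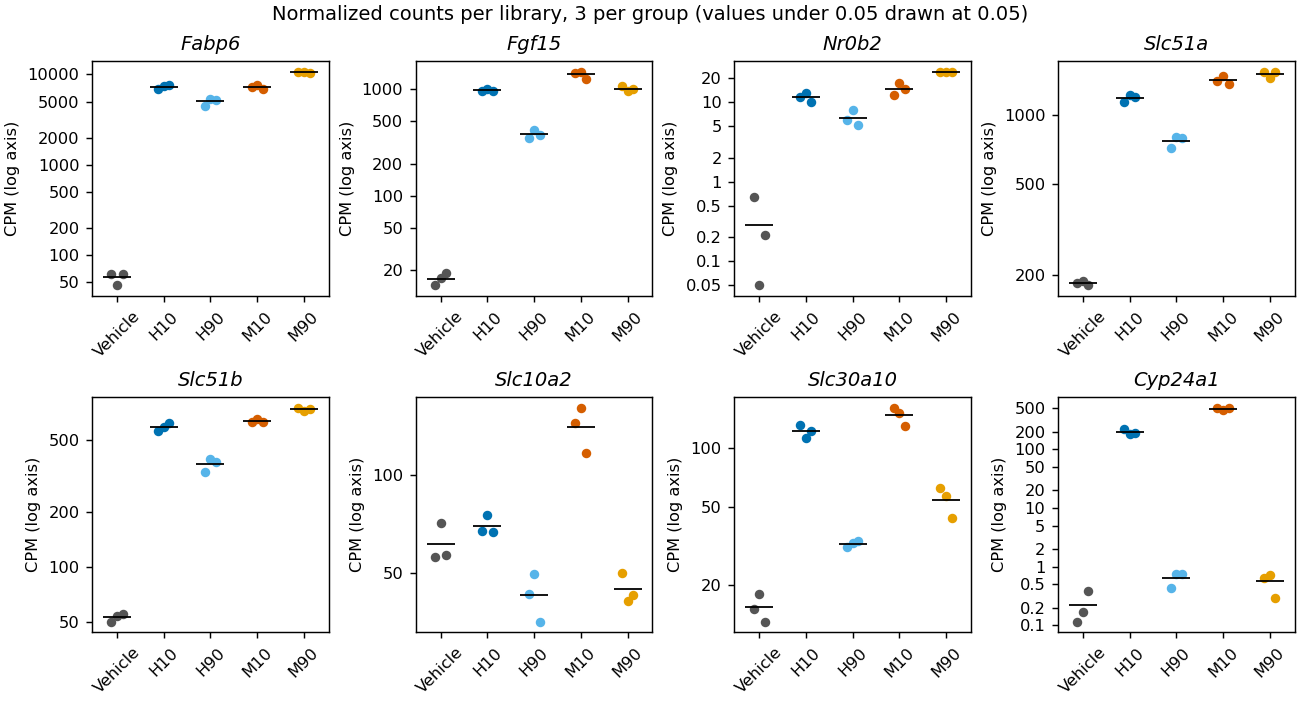
CPM (log axis) of 7 genes fixed before the data were examined (bile acid genes, and Slc30a10 as a subject of the study) and of Cyp24a1, 1 point per library with a line at each group's mean, n = 3 per group and values under 0.05 drawn at 0.05. Fabp6 goes from 56.7 CPM in vehicle to between 5018 and 10590 CPM in the pools, and Slc30a10 is higher in H10 and M10 than in H90 and M90.

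Proliferation fell in every pool. Of 34 tested proliferation genes, 34 fell on the mean of the pools (median log2 -2.54, camera adjusted p = 1.25e-20, adjusted p = 0.00288 with an estimated correlation). Top2a, the topoisomerase of dividing cells, went from 252 ± 8.00 CPM in vehicle to 6.83 ± 0.489 in M10 (log2 on the mean of the pools -2.82, SE 0.0521). Rrm1, a subunit of ribonucleotide reductase, changed by -2.36 (SE 0.0590) and Mcm6, of the replicative helicase, by -2.27 (SE 0.0641). Stem cell markers gave 0 higher and 18 lower of 21 (1 and 19 adjusted over the list alone), median log2 -0.85, camera adjusted p = 7.12e-07, adjusted p = 0.0231 with an estimated correlation. Among them were Olfm4 (-6.27, SE 0.140) and the Wnt target Axin2 (-2.75, SE 0.0886). The 10 largest falls with CPM ranges apart from vehicle include E2f7 (-4.06), Esco2 (-3.81), Mxd3 (-3.73) and Rad51ap1 (-3.72) (SEs 0.183 to 0.313). Exo1 and Fanci, also among them, had no count in any M10 library. At a floor of 3 counts per library (0.132 CPM), which covers counting error only, they lie at least 82.4-fold and 72.6-fold below vehicle there. Beside Olfm4 the other falls included the amino acid transporter Slc6a14 (-4.16, SE 0.226) and Slfn9 (-3.83, SE 0.153).

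Lipid handling rose. All 27 tested genes of fatty acid oxidation and PPAR targets rose (median log2 0.98, camera adjusted p = 1.43e-17, adjusted p = 0.0603 with an estimated correlation). Creb3l3, a transcription factor of lipid metabolism, had a change of 2.29 (SE 0.0501), and the peroxisomal enzyme Hsd17b4 had 1.47 (SE 0.0442). Of 25 genes of lipid absorption and chylomicron assembly, 24 rose (median log2 0.86, camera adjusted p = 6.32e-15, adjusted p = 0.0540 with an estimated correlation). Among them were Cidec, a lipid droplet protein (2.05, SE 0.0598), and Mttp, which loads lipid onto apolipoprotein B (1.098, SE 0.0343). After Fabp6, Nr0b2 and Fgf15 the largest rises with CPM ranges apart from vehicle were Pdk4 (4.32), Cyp4a10 (4.27), Acacb (4.25), Plb1 (4.11), Acot12 (3.81), Fabp1 (3.68) and Acaa1b (3.66) (SEs 0.0862 to 0.330). Cyp24a1 rose more on the mean of the pools (5.85) than Nr0b2 or Fgf15, but its CPM range in the pools overlaps that of vehicle. The FXR target list gave 8 higher and 1 lower of 16, median log2 0.58, camera adjusted p = 0.000127, adjusted p = 0.0603 with an estimated correlation. Beside the exporter subunits it holds the canalicular exporter Abcc2 (1.07, SE 0.0391) and Apoc2 (2.03, SE 0.0820). Xenobiotic genes of PXR, CAR and VDR gave 22 higher and 3 lower of 27, median log2 0.68, camera adjusted p = 5.29e-09, adjusted p = 0.0603 with an estimated correlation. The carboxylesterase Ces2a had 1.17 (SE 0.0373) there.

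Markers of differentiated and secretory cells were mostly higher. Enterocyte genes gave 25 higher and 2 lower of 32 (26 and 2 adjusted over the list alone), median log2 0.54, camera adjusted p = 4.80e-08, adjusted p = 0.0651 with an estimated correlation. Their member with the smallest p was Krt20 (1.07, SE 0.0324). Goblet cell genes gave 15 higher and 1 lower of 20, median log2 0.998, camera adjusted p = 7.17e-07, adjusted p = 0.0540 with an estimated correlation. The mucus proteins Zg16 and Tff3 changed by 3.00 (SE 0.0564) and 1.59 (SE 0.0549). Paneth cell genes gave 14 higher and 0 lower of 17 (15 and 0 adjusted over the list alone), median log2 0.98, camera adjusted p = 4.16e-05, adjusted p = 0.0651 with an estimated correlation. Enteroendocrine genes, with the hormone Cck at 1.32 (SE 0.0429), gave 22 higher and 2 lower of 30, median log2 0.69, camera adjusted p = 3.64e-06, adjusted p = 0.0603 with an estimated correlation. Tuft cell genes, with Dclk1 at 0.68 (SE 0.0797), gave 12 higher and 0 lower of 20, median log2 0.64, camera adjusted p = 0.000364, adjusted p = 0.0540 with an estimated correlation.

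Several stress and repair lists rose too, while heat shock genes fell (1 higher and 8 lower of 15, median log2 -0.23). The amino acid and ATF4 stress response gave 16 higher and 4 lower of 26, median log2 0.68, camera adjusted p = 9.31e-05, adjusted p = 0.166 with an estimated correlation. Chac1, which degrades glutathione, had 1.93 (SE 0.0800) and Ddit3, the factor CHOP, 1.497 (SE 0.0857). Repair and YAP genes gave 15 higher and 0 lower of 21, median log2 0.59, camera adjusted p = 2.38e-05, adjusted p = 0.0999 with an estimated correlation. The EGF receptor ligands Areg and Ereg changed by 2.12 (SE 0.0591) and 1.44 (SE 0.0544). Immediate early genes, with Zfp36 at 0.99 (SE 0.0413), gave 19 higher and 2 lower of 24, median log2 0.56, camera adjusted p = 2.38e-05, adjusted p = 0.105 with an estimated correlation. Interferon response genes, with H2-K1 at 0.71 (SE 0.0353), gave 16 higher and 0 lower of 31 (14 and 0 adjusted over the list alone), median log2 0.60, camera adjusted p = 0.000442, adjusted p = 0.0487 with an estimated correlation. Metal transport, a list that holds Slc30a10, gave 15 higher and 3 lower of 24 (17 and 3 adjusted over the list alone), median log2 0.23, camera adjusted p = 0.000683, adjusted p = 0.0760 with an estimated correlation. The zinc exporter Slc30a1 had 1.09 (SE 0.0595) there. With library size as the only scaling the metal transport list gave 10 higher and 5 lower, median log2 0.09.

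Antimicrobial genes went down on the mean of the pools, mostly through M10 and M90. That list gave 3 higher and 10 lower of 17 (3 and 11 adjusted over the list alone), median log2 -1.05, camera adjusted p = 0.0124, adjusted p = 0.0651 with an estimated correlation. Its median was -0.09 in H10 (2 higher and 7 lower) and -0.25 in H90 (3 and 3). In M10 it was -2.10 (3 and 11) and in M90 -0.99 (3 and 12), and both pools differ in library set from vehicle. Pigr, which carries IgA across the epithelium, changed by -1.05 (SE 0.0278), the bactericidal lectin Reg3g by -0.89 (SE 0.0355) and Dmbt1 by -3.36 (SE 0.0640). Its members Saa1 and Saa2 are also liver transcripts and split by library set. In all, 7625 of 13159 tested genes changed (3640 higher and 3985 lower, 1574 of them at least 2-fold). The test was edgeR quasi-likelihood with 10 residual degrees of freedom and a Benjamini-Hochberg adjusted p under 0.05. With library set as a term 5196 genes passed. With library size as the only scaling, which shifts the median of all genes by -0.15 log2, 30.8% of the called genes were higher in place of 47.7%. Of 24 lists called with a preset correlation, 3 kept the call with an estimated one, and adjusted p of the rest lay between 0.0540 and 0.396 there (at most 0.0693 under the other alternatives).

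**Figure D3:**
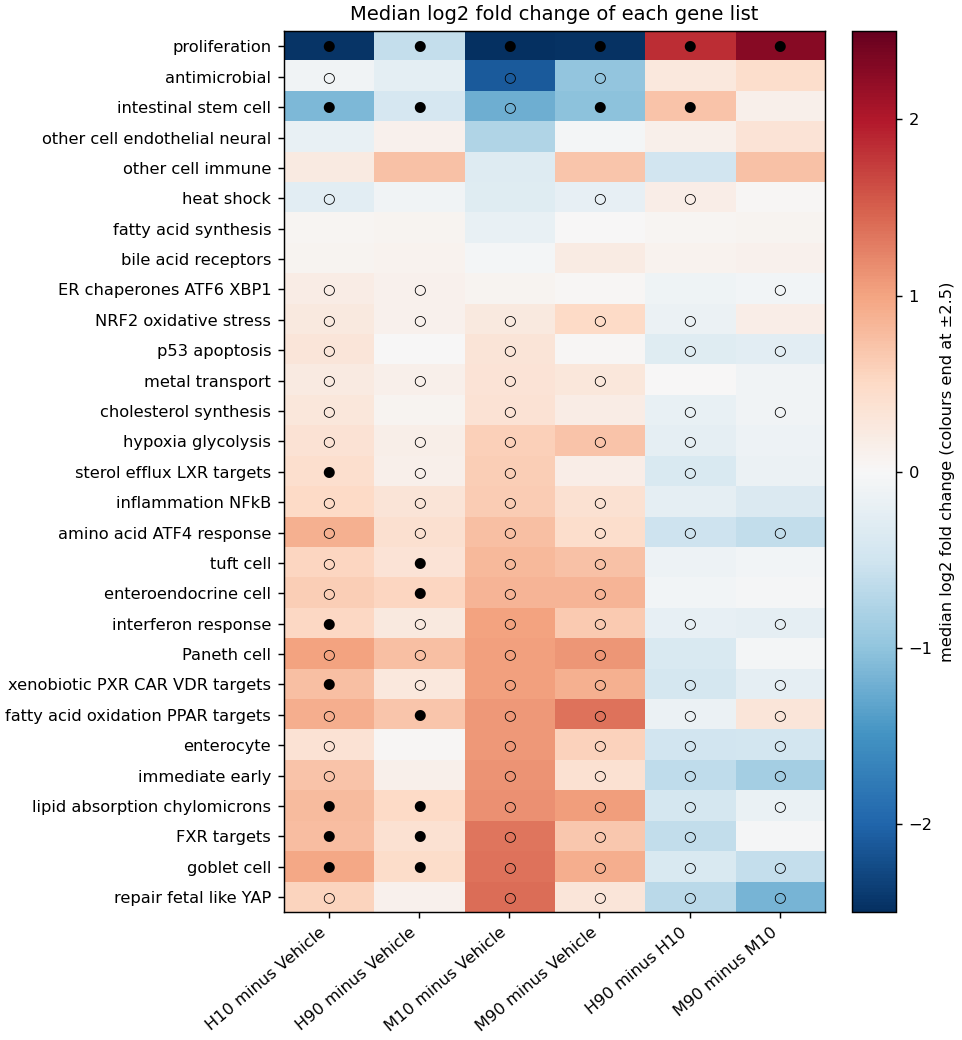
Median log2 change of the members of each of 29 tested gene lists (colour, ending at ±2.5) in 6 comparisons, with a filled dot where the camera call holds with an estimated correlation and an open dot where it holds with the preset correlation alone. Proliferation has a median of -4.59 in M10 minus vehicle, 1.85 in H90 minus H10 and 2.28 in M90 minus M10.

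Against vehicle alone, the pools differed in the size of these changes, and H90 did not show all of them. No direction passed in H90 for enterocyte genes (9 higher and 7 lower of 32, 11 and 10 adjusted over the list alone, median log2 0.02, camera adjusted p = 0.471, adjusted p = 0.792 with an estimated correlation) or repair and YAP genes (6 higher and 0 lower of 21, 7 and 1 adjusted over the list alone, median log2 0.11, camera adjusted p = 0.0543, adjusted p = 0.475 with an estimated correlation). Nor did it for immediate early genes (5 higher and 2 lower of 24, median log2 0.13, camera adjusted p = 0.210, adjusted p = 0.644 with an estimated correlation) or antimicrobial genes (3 higher and 3 lower of 17, 3 and 4 adjusted over the list alone, median log2 -0.25, camera adjusted p = 0.158, adjusted p = 0.258 with an estimated correlation). Proliferation genes fell most in M10 and least in H90. Their median log2 change was -2.44 in H10 (34 of 34 fell, camera adjusted p = 3.29e-22, adjusted p = 0.00213 with an estimated correlation). In H90 it was -0.59 (30 fell, 31 adjusted over the list alone, camera adjusted p = 4.79e-12, adjusted p = 0.0266 with an estimated correlation). In M10 it was -4.59 (34 fell, camera adjusted p = 4.17e-20, adjusted p = 0.00320 with an estimated correlation), and in M90 -2.47 (34 fell, camera adjusted p = 4.87e-20, adjusted p = 0.00345 with an estimated correlation). Cyp24a1, which inactivates vitamin D, was the largest rise in H10 (9.73, SE 0.151, from 0.225 ± 0.143 to 199.5 ± 20.1 CPM) and in M10 (11.03, SE 0.146, to 493 ± 22.3 CPM).

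The other largest rises in H10 were Fabp6 (7.02), Fgf15 (5.84), Nr0b2 (5.596) and Plb1 (4.40) (SEs 0.0922 to 0.379), and the falls Olfm4 (-7.46), Slc6a14 (-3.94), Dmbt1 (-3.92), Kcne3 (-3.58) and Nmral1 (-3.45) (SEs 0.103 to 0.383). H90 raised Fabp6 (6.48), Nr0b2 (4.74), Fgf15 (4.48), Cyp4a10 (4.11) and Acacb (3.94) (SEs 0.0893 to 0.402) most and lowered Susd2 (-3.81), Slc6a14 (-2.78), Lipn (-2.21), Olfm4 (-2.02) and Slc5a12 (-1.72) (SEs 0.160 to 0.415). M10 raised Fabp6 (7.02), Fgf15 (6.34) and Nr0b2 (5.93) (SEs 0.0936 to 0.373). It lowered Exo1 and Fanci to 0 counts and Esco2 (-9.04), E2f7 (-8.55) and Olfm4 (-8.42) (SEs 0.274 to 0.494). M90 raised Fabp6 (7.55), Nr0b2 (6.63), Cyp4a10 (6.01) and Fgf15 (5.90) (SEs 0.0924 to 0.365) and lowered Olfm4 (-7.18) and Slc6a14 (-5.48) (SEs 0.243 to 0.409). By rank Col1a1 belongs to the rises in M10 (7.56, SE 1.69) and M90 (7.51, SE 1.69). The M90 falls likewise include Saa2 (-6.81, SE 1.74), Mup20 (-5.48, SE 1.35) and Saa1 (-4.90, SE 1.15). These 4 genes follow the library sets, and with set as a term none of them passes and Col1a1 has no usable estimate.

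Slc30a10 rose in each pool by edgeR. Its fold change was 7.90 in H10 (log2 2.98, SE 0.132, adjusted p = 1.37e-12) and 2.09 in H90 (1.07, SE 0.138, adjusted p = 1.70e-05). In the mouse-like pools it was 9.49 in M10 (3.25, SE 0.132, adjusted p = 1.61e-13) and 3.51 in M90 (1.81, SE 0.133, adjusted p = 1.76e-09). Slc10a2 rose in M10 (1.20, SE 0.135, adjusted p = 1.75e-06) and did not pass in H10 (0.18, 95% interval -0.11 to 0.48). It fell in H90 (-0.52, SE 0.142, adjusted p = 0.0178) and M90 (-0.47, SE 0.140, adjusted p = 0.0112), and both calls end with library set as a term. Nr1h4 rose in H10 (0.52, SE 0.0527), M10 (0.62, SE 0.0525) and M90 (0.45, SE 0.0526) and did not pass in H90 (0.07, 95% interval -0.04 to 0.18). In H10, H90, M10 and M90 Slc51a rose by 2.69, 2.07, 2.94 and 3.04, and Slc51b by 3.48, 2.80, 3.59 and 3.80. The FXR target list was called in H10 (camera adjusted p = 2.54e-06, adjusted p = 0.0395 with an estimated correlation) and H90 (camera adjusted p = 1.34e-05, adjusted p = 0.0373 with an estimated correlation). It was also called in M10 (camera adjusted p = 0.000300, adjusted p = 0.0694 with an estimated correlation) and M90 (camera adjusted p = 0.000528, adjusted p = 0.0574 with an estimated correlation).

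By edgeR 6380 genes changed in H10 (3161 higher, 3219 lower) and 2840 in H90 (1542 and 1298). M10 changed 8482 (4103 and 4379) and M90 7199 (3451 and 3748). In all 4 pools 1236 genes were higher and 908 lower, and 300 were called both ways in different pools. M10 and M90 shared 2854 rises and 3104 falls, where independent calls would share 1076 and 1247. H10 and M10 shared 2925 and 2954 (independent 986 and 1071). H10 and H90 shared 1317 and 995 (independent 370.4 and 318). The remaining pairs shared 2636 and 2802 (H10 and M90), 1301 and 957 (H90 and M10) and 1451 and 1157 (H90 and M90). All pairs share the 3 vehicle libraries, which cannot be divided, and 20 simulated runs with no effect shared at most 1 gene in any pair. Those runs held no difference between library sets and gave all groups the same spread. They cannot tell calls shared through treatment from calls shared through set, as where M10 and M90 both differ in set from vehicle. Nor do they hold the wider spread of H90 and M10. The covariance of log2 changes was 0.961 for M10 and M90 against 0.0472 simulated, and 0.263 against 0.0471 for H10 and H90. For H90 and M10 it was 0.345 against 0.0465. Independent calls of this pair would share 480.8 rises and 431.9 falls, where 1301 and 957 were shared. Another 186 genes were called in opposite directions. The correlation of this pair was 0.493 against 0.484 simulated with no effect. Sharing vehicle alone gave simulated correlations of 0.482 to 0.502 over all pairs. Likeness to that value therefore cannot tell whether the changes in H90 and M10 were alike.

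With library set as a term 6447, 1069, 5809 and 3958 genes passed in H10, H90, M10 and M90. Within set 1 the counts were 7205 for H10 and 1687 for H90, which has 1 library there and takes its spread from the others. Library size as the only scaling shifts the median by -0.13, -0.26 and -0.15 log2 in H10, M10 and M90. The share of higher genes then goes from 49.5 to 33.3% in H10, 54.3 to 42.5% in H90, 48.4 to 29.5% in M10 and 47.9 to 31.9% in M90.

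H90 minus H10 asks what a higher 12α-hydroxylated share does in the human-like pools. Organoids in H90 were closer to vehicle. All 34 proliferation genes were higher in H90 than in H10 (median log2 1.85, camera adjusted p = 6.80e-26, adjusted p = 0.00111 with an estimated correlation). Top2a had 165 ± 21.0 CPM in H90 and 37.7 ± 4.14 in H10 (log2 2.14, SE 0.0773). Stem cell markers gave 14 higher and 0 lower of 21, median log2 0.71, camera adjusted p = 7.24e-07, adjusted p = 0.0240 with an estimated correlation. Cyp24a1 was the largest fall, from 199.5 ± 20.1 to 0.651 ± 0.190 CPM (log2 -8.34, SE 0.138, adjusted p = 2.17e-29). S100g, the calcium-binding protein calbindin-D9k, went from 680.2 ± 40.7 to 117 ± 13.4 CPM (-2.55, SE 0.114). Slc30a10 went from 123 ± 9.42 to 32.7 ± 1.29 CPM (-1.92, SE 0.125, adjusted p = 1.01e-09). The other bile acid genes were lower too: Fgf15 (-1.37), Nr0b2 (-0.86), Slc10a2 (-0.70), Slc51b (-0.68), Slc51a (-0.62), Fabp6 (-0.55) and Nr1h4 (-0.44) (SEs 0.0446 to 0.241). The FXR list gave 0 higher and 9 lower of 16, median log2 -0.62, camera adjusted p = 2.23e-05, adjusted p = 0.0663 with an estimated correlation.

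Several differentiation and stress lists were lower in H90 than in H10. Heat shock genes went the other way (7 higher and 1 lower of 15, median log2 0.16). Few enteroendocrine (2 higher and 4 lower of 30) and tuft cell markers (0 and 2 of 20) were called. Enterocyte genes gave 0 higher and 25 lower of 32, median log2 -0.47, camera adjusted p = 4.09e-11, adjusted p = 0.0663 with an estimated correlation. Goblet cell genes gave 1 higher and 12 lower of 20, median log2 -0.38, camera adjusted p = 7.75e-06, adjusted p = 0.0778 with an estimated correlation. Lipid absorption genes gave 0 higher and 19 lower of 25, median log2 -0.44, camera adjusted p = 3.03e-09, adjusted p = 0.0881 with an estimated correlation. The ATF4 response, with Chac1 at -1.38 (SE 0.0870), gave 1 higher and 19 lower of 26 (2 and 19 adjusted over the list alone), median log2 -0.52, camera adjusted p = 6.03e-08, adjusted p = 0.0881 with an estimated correlation. For repair and YAP genes, with Ereg at -1.38 (SE 0.0630), the result was 0 higher and 14 lower of 21 (1 and 14 adjusted over the list alone), median log2 -0.68, camera adjusted p = 3.13e-06, adjusted p = 0.0944 with an estimated correlation. For immediate early genes, with Klf6 at -0.75 (SE 0.0469), it was 1 higher and 16 lower of 24 (1 and 17 adjusted over the list alone), median log2 -0.64, camera adjusted p = 3.42e-07, adjusted p = 0.0881 with an estimated correlation. Fatty acid oxidation genes gave 2 higher and 14 lower of 27 (2 and 17 adjusted over the list alone), median log2 -0.16, camera adjusted p = 0.00539, adjusted p = 0.521 with an estimated correlation. With library size as the only scaling 5 of them were higher and 9 lower, median log2 -0.06.

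Among the 10 largest rises in H90 over H10 were Olfm4 (5.44), Dmbt1 (3.08), Nmral1 (2.84) and Ankle1 (2.83) (SEs 0.102 to 0.387). So were Kcne3 (2.82), Rad54b (2.82), Suv39h2 (2.80), Fignl1 (2.77) and Myb (2.76) (SEs 0.158 to 0.402). Beside Cyp24a1, S100g and Slc30a10 the 10 largest falls were Gpr137b (-2.59), Mmp23 (-2.09), Clca3 (-1.92) and H2-Q1 (-1.74) (SEs 0.0622 to 0.505), and Jdp2 (-1.67), Plb1 (-1.62) and Rin1 (-1.61) (SEs 0.0996 to 0.133). The Mmp23 call ends with library set as a term. In all, 4815 of 13159 tested genes changed (2398 higher and 2417 lower, 703 of them at least 2-fold) by edgeR. With library set as a term 3479 passed, and 4284 with H90 a as the only H90 library, whose spread is then taken from the other libraries. Nr0b2 no longer passed there, at -0.97 (SE 0.371, adjusted p = 0.0511) after -0.86 (SE 0.241), so its change was no smaller. Library size as the only scaling takes the share of higher genes from 49.8 to 66.9%. Of 18 lists called, 2 held with an estimated correlation, where adjusted p of the rest lay between 0.0663 and 0.648 (at most 0.112 under the other alternatives).

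M90 minus M10 puts the same question to the mouse-like pools, with all 6 libraries in set 2. Proliferation genes were again higher at 90% (33 higher and 0 lower of 34, median log2 2.28, camera adjusted p = 2.89e-21, adjusted p = 0.00255 with an estimated correlation). Top2a had 38.4 ± 0.483 CPM in M90 and 6.83 ± 0.489 in M10 (log2 2.498, SE 0.0964). Cyp24a1 fell from 493 ± 22.3 to 0.564 ± 0.233 CPM (log2 -9.77, SE 0.131, adjusted p = 3.58e-32), and S100g from 1003 ± 93.5 to 280.1 ± 32.7 CPM (-1.84, SE 0.108). Slc30a10 fell from 148 ± 16.0 to 54.7 ± 9.60 CPM (-1.43, SE 0.118, adjusted p = 1.76e-08), and Slc10a2 from 141 ± 22.3 to 44.7 ± 4.80 CPM (-1.67, SE 0.139). The remaining bile acid genes moved both ways. Fabp6 (0.53, SE 0.0992, adjusted p = 0.00113), Nr0b2 (0.69, SE 0.219, adjusted p = 0.0131) and Slc51b (0.21, SE 0.0485, adjusted p = 0.000425) were higher in M90. Fgf15 (-0.44, SE 0.0697, adjusted p = 4.30e-05) and Nr1h4 (-0.16, SE 0.0520, adjusted p = 0.0111) were lower, and Slc51a did not pass (0.09, 95% interval 0.00 to 0.18). The Nr0b2 call ends without M10 a, and the Nr1h4 call without M90 b or with library size or upper-quartile scaling. The FXR list gave 3 higher and 5 lower of 16, median log2 -0.03, camera adjusted p = 0.408, adjusted p = 0.650 with an estimated correlation, and its median is above 0 with library size or upper-quartile scaling.

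Fatty acid oxidation genes were higher in M90 (21 higher and 2 lower of 27, median log2 0.31, camera adjusted p = 9.25e-06, adjusted p = 0.348 with an estimated correlation). Acaa1b and Cyp4a10, 2 targets of PPARα, changed by 1.34 (SE 0.0764) and 2.87 (SE 0.212). Lipid absorption genes were lower (3 higher and 13 lower of 25, median log2 -0.17, camera adjusted p = 0.000472, adjusted p = 0.344 with an estimated correlation). With library size as the only scaling 6 of them were higher and 10 lower, median log2 -0.06. Apoa4, an apolipoprotein of chylomicrons, went from 2567 ± 166 to 628 ± 67.2 CPM. Enterocyte genes were lower (2 higher and 25 lower of 32, median log2 -0.45, camera adjusted p = 2.59e-09, adjusted p = 0.134 with an estimated correlation). Goblet cell genes, with Zg16 at -1.30 (SE 0.0565), were lower (0 higher and 13 lower of 20, median log2 -0.59, camera adjusted p = 6.01e-06, adjusted p = 0.119 with an estimated correlation). ATF4 genes were lower (2 higher and 19 lower of 26, median log2 -0.62, camera adjusted p = 1.17e-07, adjusted p = 0.164 with an estimated correlation). So were repair and YAP genes, with Krt7 at -0.88 (SE 0.0485) (0 higher and 17 lower of 21, median log2 -1.17, camera adjusted p = 1.84e-10, adjusted p = 0.111 with an estimated correlation). Immediate early genes, with Egr1 at -1.22 (SE 0.0886), were lower as well (0 higher and 19 lower of 24, median log2 -0.85, camera adjusted p = 1.84e-10, adjusted p = 0.111 with an estimated correlation).

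Among the 10 largest rises in M90 over M10, Exo1 and Fanci were at least 12.5-fold and 7.89-fold lower in M10 by the floor. The others were Esco2 (6.43), Rad51ap1 (5.37), Mxd3 (5.36) and Rad54l (5.20) (SEs 0.502 to 0.850), and Cenpm (5.17), E2f7 (4.92), Timeless (4.79) and Troap (4.49) (SEs 0.451 to 0.655). After Cyp24a1 the largest falls were Psca (-2.59), Clca6 (-2.49), Pmp22 (-2.41), Fkbp5 (-2.29) and Prrg4 (-2.26) (SEs 0.117 to 0.220), and Akp3 (-2.23), Apoa4 (-2.03), Calcb (-1.92) and Tubb2a (-1.90) (SEs 0.0749 to 0.323), of which Fkbp5 is a glucocorticoid-inducible co-chaperone. In all, 5428 of 13159 tested genes changed (2799 higher and 2629 lower, 809 of them at least 2-fold) by edgeR. With set as a term 5522 passed, and 4860 from set 2 alone. Library size as the only scaling shifts the median by 0.11 log2 and takes the share of higher genes from 51.6 to 69.7%, and upper-quartile scaling to 65.4%. Of 13 lists called, 1 held with an estimated correlation (the rest between 0.111 and 0.541, at most 0.0525 under the other alternatives).

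Whether the 12α-hydroxylated share acted alike in both models was asked over all genes and gene by gene. Across 13159 genes the changes H90 minus H10 and M90 minus M10 correlated with Pearson r = 0.508 (jackknife SE over libraries 0.0889) and Spearman rho = 0.52. Genes are not independent replicates, and with 99 exchanges of the 10% and 90% labels r reached at most 0.318. Its lowest, -0.508, is the real value with the sign turned by exchanging all labels of 1 model, and other exchanges keep part of the effect. With library set as a term r was 0.421, with no filter 0.151 and with at least 1 CPM in 3 libraries 0.619. Both contrasts called 1434 genes higher, 1563 lower and 195 in opposite directions, where independent calls would share 510.1 and 482.9. The difference between the 2 contrasts passed the edgeR test for 1943 genes. With library set as a term 1442 passed, and 1288 of these were among the 1943 with the same direction. H90 minus H10 crosses the sets, while M90 minus M10 lies in set 2. Without that term the difference was positive for 1033 and negative for 910 (53.2% positive, 58.6% with library size as the only scaling and 62.3% with upper-quartile scaling). It was positive for Fabp6 (1.08, SE 0.140, adjusted p = 0.000346), Nr0b2 (1.55, SE 0.325, adjusted p = 0.00146) and Fgf15 (0.92, SE 0.0993, adjusted p = 3.38e-06). So it was for Slc51b (0.89, SE 0.0691, adjusted p = 7.99e-12), Slc51a (0.71, SE 0.0628, adjusted p = 1.01e-10) and Nr1h4 (0.28, SE 0.0742, adjusted p = 0.00783), and it was negative for Slc10a2 (-0.97, SE 0.197, adjusted p = 0.00405). Slc30a10 did not pass (0.48, 95% interval 0.12 to 0.84, adjusted p = 0.0681), though it does under several alternatives.

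Lists with more positive 90% minus 10% differences in the mouse-like pools were fatty acid oxidation genes (22 higher and 0 lower of 27, 24 and 0 adjusted over the list alone, median log2 0.54, camera adjusted p = 4.44e-16, adjusted p = 0.256 with an estimated correlation), FXR targets (7 higher and 2 lower of 16, median log2 0.77, camera adjusted p = 0.00182, adjusted p = 0.256 with an estimated correlation) and NRF2 oxidative stress genes (12 higher and 0 lower of 25, 14 and 0 adjusted over the list alone, median log2 0.21, camera adjusted p = 3.64e-07, adjusted p = 0.291 with an estimated correlation). Stem cell markers moved both ways in M90 minus M10 (4 higher and 4 lower of 21, median log2 0.13). In H90 minus H10 they rose (14 higher and 0 lower, median log2 0.71). They thus had more negative differences (0 higher and 11 lower of 21, 0 and 15 adjusted over the list alone, median log2 -0.70, camera adjusted p = 7.74e-09, adjusted p = 0.0141 with an estimated correlation). So had repair and YAP genes (1 higher and 9 lower of 21, median log2 -0.31, camera adjusted p = 0.000716, adjusted p = 0.462 with an estimated correlation) and immediate early genes (0 higher and 4 lower of 24, median log2 -0.18, camera adjusted p = 0.0125, adjusted p = 0.735 with an estimated correlation). Xenobiotic genes gave 11 higher and 4 lower of 27 (13 and 4 adjusted over the list alone), median log2 0.17, camera adjusted p = 0.0117, adjusted p = 0.735 with an estimated correlation. Proliferation genes did not pass (13 higher and 6 lower of 34, 14 and 10 adjusted over the list alone, median log2 0.38, camera adjusted p = 0.547, adjusted p = 0.838 with an estimated correlation). The largest upward differences were Esco2 (4.28), Cenpm (3.71) and Rad51ap1 (3.69) (SEs 0.597 to 0.890), with Exo1 and Fanci of no measured size because M10 has no counts of them. Downward they were Col1a1 (-6.42), Olfm4 (-4.20), Fkbp5 (-3.32), Psca (-2.79) and Rpph1 (-2.24) (SEs 0.178 to 1.96), and Col1a1 has no usable estimate with set as a term. Adjusted p of the 6 lists lost with an estimated correlation lay between 0.256 and 0.735, and under the other alternatives reached 0.207.

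**Figure D4:**
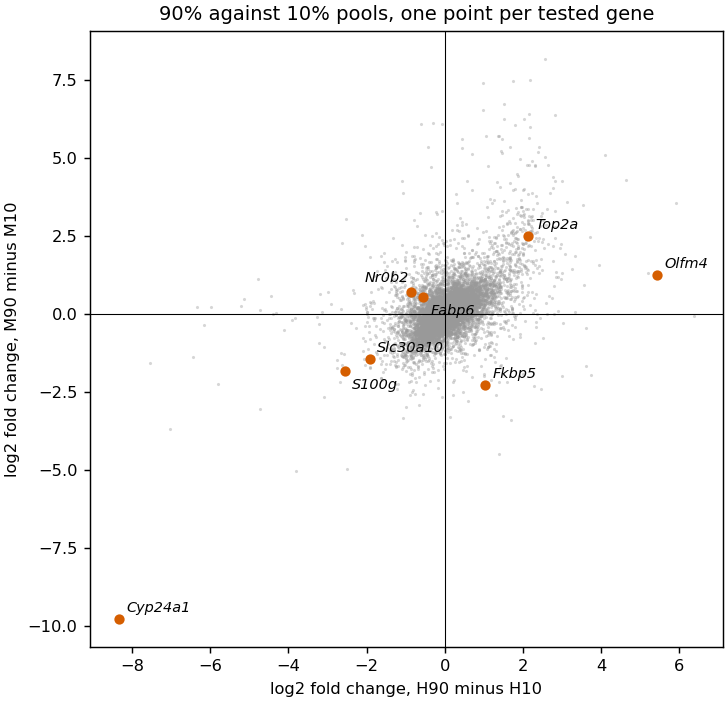
Log2 change of each tested gene in H90 minus H10 (x axis) and M90 minus M10 (y axis), with 8 genes named (Pearson r = 0.508). Cyp24a1 lies at -8.34 and -9.77, and genes with no counts in M10 have no measured size on the y axis.

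M10 minus H10 compares the species models at a 10% share, between libraries of different sets. Proliferation was lower in M10 (0 higher and 33 lower of 34, 0 and 34 adjusted over the list alone, median log2 -2.29, camera adjusted p = 4.78e-26, adjusted p = 0.00109 with an estimated correlation). Top2a had -2.47 (SE 0.0969), and the mitotic genes Aurka and Cdc20 had -3.41 (SE 0.165) and -2.79 (SE 0.136). Enterocyte genes were higher (25 higher and 1 lower of 32, 27 and 2 adjusted over the list alone, median log2 0.55, camera adjusted p = 1.88e-13, adjusted p = 0.0786 with an estimated correlation). Lipid absorption genes, with Cidec at 1.38 (SE 0.0610), were higher (21 higher and 1 lower of 25, median log2 0.33, camera adjusted p = 2.17e-11, adjusted p = 0.0951 with an estimated correlation). Repair and YAP genes, with Clu at 1.99 (SE 0.0955), were higher (16 higher and 0 lower of 21, median log2 0.84, camera adjusted p = 2.83e-09, adjusted p = 0.0907 with an estimated correlation). Goblet cell genes, with Zg16 at 1.79 (SE 0.0574), were higher (13 higher and 0 lower of 20, 14 and 0 adjusted over the list alone, median log2 0.44, camera adjusted p = 4.73e-06, adjusted p = 0.0907 with an estimated correlation). Antimicrobial genes gave 3 higher and 10 lower of 17, median log2 -1.27, camera adjusted p = 0.0137, adjusted p = 0.0951 with an estimated correlation. Of that list Saa1 and Saa2 follow the library sets, and Pigr and Reg3g had -1.25 (SE 0.0384) and -1.498 (SE 0.0493).

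Of the bile acid genes, Slc10a2 (1.02, SE 0.135, adjusted p = 3.05e-05), Fgf15 (0.50, SE 0.0698, adjusted p = 1.45e-05) and Slc51a (0.26, SE 0.0443, adjusted p = 1.39e-05) were higher in M10 than in H10. The last 2 calls end with set as a term. No difference passed for Fabp6 (-0.00, 95% interval -0.22 to 0.22), Nr0b2 (0.34, -0.13 to 0.80) or Nr1h4 (0.10, -0.01 to 0.21). Slc51b (0.11, 0.01 to 0.21) and Slc30a10 (0.26, 0.02 to 0.50) did not pass either, since the interval of 1 gene takes no account of the adjustment over all genes.

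The largest rises in M10 over H10 were Col1a1 (6.93), Fkbp5 (3.49), Cyp27a1 (3.19), Psca (3.11) and Sgk1 (2.80) (SEs 0.121 to 1.59), and Apoc2 (2.66), Apoa4 (2.64), Vwa1 (2.37), Clca6 (2.16) and Oas3 (2.09) (SEs 0.0768 to 0.337). Cyp27a1 is sterol 27-hydroxylase, and Sgk1 a kinase induced by corticosteroids. With set as a term Col1a1 and Vwa1 are not called. The largest falls were Exo1 and Fanci, at least 9.09-fold and 8.82-fold, and Esco2 (-6.17), Rad51ap1 (-5.64), E2f7 (-5.41), Rad54l (-5.03) and Mxd3 (-5.00) (SEs 0.519 to 0.890). The liver transcripts Saa2 (-7.62), Saa1 (-5.83) and Mup20 (-5.78) (SEs 1.25 to 1.79) are among them too, and all 3 lose the call with set as a term. In all, 4779 of 13159 tested genes changed (2394 higher and 2385 lower, 756 of them at least 2-fold) by edgeR. With set as a term 2025 passed, and no set holds both groups. Library size as the only scaling shifts the median by -0.13 log2 and takes the share of higher genes from 50.1 to 25.1% (upper quartile 35.5%). Of 14 lists called, 1 held with an estimated correlation (the rest between 0.0786 and 0.624, up to 0.278 under the other alternatives). With set as a term 8 were kept, and those lost were xenobiotic genes (adjusted p = 0.278), enteroendocrine (0.278) and tuft cell markers (0.135), NFkB inflammation (0.156), antimicrobial (0.0541) and glycolysis and hypoxia genes (0.0618). With RLE 12 lists were called.

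M90 minus H90 compares the species models at a 90% share. Here the bile acid genes were higher in the mouse-like pool. Fabp6 had 10590 ± 124 CPM in M90 and 5018 ± 489 in H90 (log2 1.08, SE 0.100). Higher too were Nr0b2 (1.89), Fgf15 (1.42), Slc51b (1.003), Slc51a (0.97), Slc30a10 (0.75) and Nr1h4 (0.38) (SEs 0.0448 to 0.237). Slc10a2 did not pass (0.05, 95% interval -0.26 to 0.36). Adjusted p of the 7 that passed by edgeR ran from 4.86e-19 (Slc51a) to 0.000123 (Slc30a10). The FXR list gave 10 higher and 0 lower of 16, median log2 0.75, camera adjusted p = 0.000161, adjusted p = 0.0526 with an estimated correlation.

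Fatty acid oxidation genes were higher in M90 than in H90 (27 higher and 0 lower of 27, median log2 0.64, camera adjusted p = 2.55e-18, adjusted p = 0.0657 with an estimated correlation). So were lipid absorption genes, with Cidec at 1.36 (SE 0.0664) (24 higher and 1 lower of 25, median log2 0.55, camera adjusted p = 5.84e-15, adjusted p = 0.0493 with an estimated correlation). Enterocyte genes, with Gda at 1.34 (SE 0.0826), were higher (29 higher and 0 lower of 32, median log2 0.54, camera adjusted p = 8.73e-15, adjusted p = 0.0493 with an estimated correlation). Interferon response genes were higher (12 higher and 0 lower of 31, median log2 0.41, camera adjusted p = 0.00202, adjusted p = 0.0493 with an estimated correlation). Proliferation genes, with Top2a at -2.11 (SE 0.0768), were lower (0 higher and 34 lower of 34, median log2 -1.86, camera adjusted p = 4.42e-25, adjusted p = 0.00128 with an estimated correlation). Stem cell markers, with Axin2 at -2.25 (SE 0.133), were lower (0 higher and 16 lower of 21, 0 and 18 adjusted over the list alone, median log2 -0.75, camera adjusted p = 1.77e-07, adjusted p = 0.0161 with an estimated correlation). Antimicrobial genes, Saa1 and Saa2 among them, were lower (2 higher and 9 lower of 17, 2 and 10 adjusted over the list alone, median log2 -0.75, camera adjusted p = 0.00365, adjusted p = 0.0526 with an estimated correlation).

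Of the 10 largest rises 5 were Chrna2 (2.85), Gpr137b (2.67), Acot12 (2.25), Mmp23 (2.25) and Pdk4 (2.10) (SEs 0.210 to 0.513). The others were Zg16 (2.06), Aqp3 (1.97), Cyp1a1 (1.95), Vwa1 (1.93) and Acaa1b (1.92) (SEs 0.0592 to 0.335), of which Aqp3 is an aquaglyceroporin and Cyp1a1 a target of the aryl hydrocarbon receptor. The 10 largest falls included Olfm4 (-5.16), Hao2 (-3.49), Slfn9 (-3.08) and Myb (-2.82) (SEs 0.157 to 0.423), and Fignl1 (-2.82), E2f7 (-2.72), Slc6a14 (-2.70), Mcm5 (-2.60) and Bard1 (-2.58) (SEs 0.139 to 0.440). In all, 5102 of 13159 tested genes changed (2532 higher and 2570 lower, 859 of them at least 2-fold) by edgeR. With set as a term 4532 passed, and 3980 among the 5 libraries of set 2. Library size as the only scaling shifts the median by -0.11 log2 and takes the share of higher genes from 49.6 to 30.1%. Of 19 lists called, 6 held with an estimated correlation (the rest between 0.0526 and 0.431, at most 0.0865 under the other alternatives).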

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

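Tests of a liver source, of Cyp24a1 against library set and proliferation, and of low library complexity were chosen after the result was seen. The counts of other splits, the set-difference tests and the vitamin D receptor test were fixed before their own results were seen. The library sets, and the pattern of Cyp24a1, S100g and Slc30a10 that the receptor test concerns, nevertheless came from these data. The differences listed first passed the edgeR test of whether the 90% minus 10% change differs between mouse-like and human-like pools, with 1943 genes in all. Named genes with such a difference were Fgf15 (0.92), Nr0b2 (1.55), Slc51a (0.71), Slc51b (0.89), Fabp6 (1.08), Nr1h4 (0.28), Slc10a2 (-0.97), Esco2 (4.28), Cenpm (3.71), Rad51ap1 (3.69), Col1a1 (-6.42), Olfm4 (-4.20), Fkbp5 (-3.32), Psca (-2.79) and Rpph1 (-2.24), all log2. Exo1 (5.62) and Fanci (5.34) have fitted values that depend on the prior count, since M10 holds none of their counts. Lists that passed camera, by median log2 difference, were FXR targets (0.77), fatty acid oxidation (0.54), NRF2 stress (0.21), xenobiotic genes (0.17), stem cell markers (-0.70), repair and YAP genes (-0.31) and immediate early genes (-0.18), and of these the stem cell list alone passed with an estimated correlation (adjusted p = 0.0141). Of 100 drawn splits of the 12 pool libraries 6 gave at least 1943 genes. The highest, 6435, exchanges the labels of the human-like pools, and such exchanges turn the effect of the share into an interaction, so this count neither excludes chance nor speaks for it.

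Other splits were counted for the remaining contrasts too. For the mean of the pools 1 of 100 splits, the real one, gave 7625 genes or more, and the highest other gave 3122. The other splits mix treatments within groups, so real differences widen their spread and lower their counts. These counts therefore do not exclude chance, and vehicle lies wholly in set 1. For each contrast of 3 against 3 libraries 1 of 10 splits reached the real count and the highest other gave 0 genes, and 10 splits cannot give a share under 0.05. The real counts were 6380 (H10), 2840 (H90), 8482 (M10) and 7199 (M90) against vehicle, 4815 for H90 minus H10, 5428 for M90 minus M10, 4779 for M10 minus H10 and 5102 for M90 minus H90.

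The first pattern weighed is the split of libraries by liver transcripts, which crosses H90. Treatment as its cause is argued against by Mup20 at 76.2 times the mean of H90 b and c in H90 a, 3 libraries of 1 treatment. RNA of liver origin carried into 7 libraries may be the source: over 28 liver-list genes other than Mup20 the median log2 ratio of H90 a to H90 b and c was 2.12 (28 of 28 higher, interquartile range 1.54 to 2.91), though 16 of them reach 2 CPM in set 2 and 3 are in another list. The liver list was itself written after the data were seen, so these values are no independent support for that source. A set difference as the main source of the calls that cross sets is argued against by H90 b and c minus H90 a. The H90 difference was taken over the called genes outside the liver list, signed by each gene's change. It covered 4751 genes in M10 minus H10, 8456 in M10 minus vehicle and 7173 in M90 minus vehicle. Its median was 0.0637 (bootstrap over genes 0.0529 to 0.0768) of the median size of the change in M10 minus H10, 0.0468 (0.0402 to 0.0536) in M10 minus vehicle and 0.0876 (0.0789 to 0.0952) in M90 minus vehicle. Genes going both ways cancel in this median. Without signs the median difference was 0.10 log2 against 0.43, 0.12 against 0.71 and 0.11 against 0.57, and the signed ratio was at least 0.5 for 12.4, 7.92 and 11.4% of genes. All of this rests on 1 library, H90 a, and set and group cannot be told apart within vehicle, H10, M10 or M90. A smaller part from set, and set as the source for single genes, stay open.

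The second is the low number of genes at low counts in H90 and M10. Depth is argued against, since after thinning to equal depth these 6 libraries held at most 14259 detected genes and the other 9 at least 14281. That gap is narrow, rests on a single random thinning and is set by H90 a. H90 b, the next highest of the 6, held 13857. Treatment lowering weakly expressed genes stays open for H90 and for M10, since H10 and M90 are other mixtures and the counts cannot rule it out. Fewer distinct RNA molecules behind these libraries is a candidate explanation: among the 25% of genes of lowest abundance the lower of the H90 and M10 dispersions was 3.35 times the highest of the other groups. Zero counts in M10 rest on the same libraries.

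The third is Cyp24a1, S100g and Slc30a10, higher in both 10% pools than in both 90% pools. A set difference is argued against by Cyp24a1 at -9.77 log2 in M90 minus M10, libraries of 1 set. A loss of proliferating cells is argued against for Cyp24a1 alone, since H10 and M90 had proliferation medians of -2.44 and -2.47 while Cyp24a1 was 354 times higher in H10. S100g was 2.43 and Slc30a10 2.25 times higher there, which was not tested, and for these 2 it stays open. Vitamin D receptor activity, a biological hypothesis, could not be decided. Of a list of 10 targets written before that test, 5 other than Cyp24a1, S100g and Slc30a10 were tested. Of these, 2 (Atp2b1, Cyp3a11) were lower in both 90% pools while Slc37a2, Cldn2 and Cldn12 were not. Which bile acids differ between the pools was not given, so a difference in single bile acids stays untested.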

How the results depend on the processing

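Library set as a term, libraries of 1 set, leaving out the liver list and weights per group were tests chosen after seeing the data, and the others were planned. Planned changes of scaling, filter, model and test kept every count of changed genes within 1.5-fold of its value: 6339 to 7186 for H10, 2479 to 3084 for H90, 8222 to 8874 for M10 and 7096 to 7823 for M90 against vehicle, 7580 to 8034 for the mean of the pools, 4690 to 4995 for H90 minus H10, 5188 to 5860 for M90 minus M10, 4749 to 5408 for M10 minus H10, 4749 to 5478 for M90 minus H90 and 1886 to 2144 for the interaction. Without 1 library at a time they ran from 5723 to 5884, 2064 to 2956, 7966 to 8278, 6432 to 6607, 6727 to 7760, 4080 to 4524, 4545 to 5217, 3957 to 4619, 4306 to 5012 and 1493 to 2072 in that order. With library set as a term 1069 genes passed for H90 against vehicle (1687 from libraries of set 1, with 1 H90 library assumed to vary like the others), 3958 for M90 against vehicle and 2025 for M10 minus H10, which may be a loss of power where set and group nearly coincide as much as a set difference, and the cause was not tested.

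The correlation of the 90% minus 10% changes was 0.151 with no filter, 0.619 with at least 1 CPM in 3 libraries, 0.421 with library set as a term and 0.399 to 0.505 without 1 library at a time (0.399 without H90 a). The first 2 take in more and fewer weakly expressed genes by construction. For the overlap of calls between pools against vehicle, at changes of at least 1.5-fold, the pools shared 599 genes over all 4, 642 for H10 and H90, 2664 for H10 and M10, 2430 for H10 and M90, 641 for H90 and M10, 690 for H90 and M90 and 2942 for M10 and M90, fewer by construction. Of 182 list calls 33 held with an estimated correlation, and the cause was not tested for each list.

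Over named genes and alternatives 4387 results stayed, 32 were gained, 38 lost, 14 moved and 6 changed sign, and over lists 1198 stayed, 53 were gained, 176 lost, 23 moved and 0 changed sign. All 6 came with library set as a term, where none was called: Col1a1 at -2.65 (M10 minus vehicle), -2.70 (M90 minus vehicle), -3.29 (M10 minus H10) and 3.15 (interaction), with SEs of at least 108900000 that leave no usable estimate, and Mup20 at 0.70 (SE 0.540, M90 minus vehicle) and 0.41 (SE 0.545, M10 minus H10). The set term takes up their split by construction, and no change of direction is shown. Calls were lost there for Fgf15 (log2 0.50, SE 0.0698, to 0.31, SE 0.109) and Slc51a (log2 0.26, SE 0.0443, to 0.11, SE 0.0734) in M10 minus H10, where the change shrank and its SE grew, and for Slc10a2 (log2 -0.52, SE 0.142, to -0.52, SE 0.213) in H90 and Slc10a2 (log2 -0.47, SE 0.140, to -0.47, SE 0.273) in M90 against vehicle, where the SE alone grew. Nr0b2 in M90 minus M10 was lost without M10 a (0.58), and Nr1h4 there with library size only (-0.05), upper-quartile factors (-0.08) and without M90 b (-0.13). Slc30a10 in M10 minus H10 and in the interaction lay near the threshold and passed under several alternatives. With replicate letters as a block 6418, 2931, 8483, 7213, 7640, 4889, 5491, 4827, 5134 and 2031 genes passed. That block took the lists called from 24 to 23 on the mean of the pools, 13 to 12 in M90 minus M10 and 14 to 13 in M10 minus H10. No test of changed genes varied depth.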

Other observations

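Further lists are given on the mean of the pools against vehicle, with library size as the only scaling beside them where it matters. Glycolysis and hypoxia genes gave 25 higher and 2 lower of 27, median log2 0.47, camera adjusted p = 1.08e-05, adjusted p = 0.354 with an estimated correlation, with Pfkp (0.76, SE 0.0548) and Vegfa (1.53, SE 0.129). Cholesterol synthesis gave 16 higher and 6 lower of 26, median log2 0.24, camera adjusted p = 0.0261, adjusted p = 0.396 with an estimated correlation, with Hmgcs1 at 0.48 (SE 0.0314). It was near even with library size only (13 higher and 10 lower, median 0.09) and not called with library set as a term (adjusted p = 0.0693). LXR targets of sterol efflux gave 9 higher and 2 lower of 15 (9 and 3 adjusted over the list alone), median log2 0.38, camera adjusted p = 0.0135, adjusted p = 0.0603 with an estimated correlation, with the sterol transporter Abcg5 at 0.43 (SE 0.0395). Fatty acid synthesis gave 7 higher and 7 lower of 16, median log2 -0.03, camera adjusted p = 0.889, adjusted p = 0.884 with an estimated correlation, with Fads2 (-1.67, SE 0.0483) and Acacb, which is also a large rise, pulling apart, and camera's direction was up. Bile acid receptors gave 4 higher and 3 lower of 13, median log2 0.18, camera adjusted p = 0.630, adjusted p = 0.621 with an estimated correlation (3 higher and 4 lower with library size only), with Nr1i2, the receptor PXR, at 0.80 (SE 0.0454).

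Stress lists were mixed. NRF2 genes gave 14 higher and 3 lower of 25, median log2 0.18, camera adjusted p = 0.00151, adjusted p = 0.238 with an estimated correlation, with Ephx1 at 1.27 (SE 0.0427), but 12 higher and 8 lower with library size only (median 0.04). Heat shock genes gave 1 higher and 8 lower of 15 (2 and 8 adjusted over the list alone), median log2 -0.23, camera adjusted p = 0.0143, adjusted p = 0.0760 with an estimated correlation, with Hspd1 at -1.01 (SE 0.0366). Chaperones of the endoplasmic reticulum gave 14 higher and 4 lower of 25, median log2 0.11, camera adjusted p = 0.0452, adjusted p = 0.209 with an estimated correlation, with Herpud1 at 0.88 (SE 0.0415), but 7 higher and 9 lower (median -0.03) with library size only, and they were not called with library set as a term (adjusted p = 0.0554). The p53 list gave 11 higher and 4 lower of 24, median log2 0.16, camera adjusted p = 0.0576, adjusted p = 0.231 with an estimated correlation, but 7 higher and 8 lower with library size as the only scaling. NFkB inflammation genes gave 10 higher and 1 lower of 18, median log2 0.44, camera adjusted p = 0.00111, adjusted p = 0.0603 with an estimated correlation, with Ccl28 at -1.38 (SE 0.0753). Immune (0 higher and 0 lower of 5, median log2 -0.01, camera adjusted p = 0.889, adjusted p = 0.884 with an estimated correlation) and endothelial or neural markers (1 higher and 1 lower of 6, median log2 -0.17, camera adjusted p = 0.762, adjusted p = 0.799 with an estimated correlation) did not pass, and the immune list has camera's direction up and a median whose sign changes with the scaling.

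Fkbp5, Sgk1 and Per1, which are known to answer glucocorticoids, were highest in M10. Fkbp5 and Sgk1 were picked by the ranking rule. Per1, and the 3 as a group, were chosen after their values were seen, and no list of such genes was tested. Tsc22d3 was looked up beside them and its values are not given, so the 3 do not stand for such genes at large. Fkbp5 had 19.4 ± 2.41 CPM in vehicle, 7.64 ± 0.501 in H10, 15.6 ± 1.46 in H90, 85.9 ± 6.24 in M10 and 17.6 ± 3.56 in M90. Sgk1 had 7.54 ± 0.191, 12.3 ± 1.03, 8.82 ± 2.49, 85.3 ± 3.12 and 29.8 ± 1.14 CPM in the same order, and Per1 22.7, 24.0, 22.4, 74.2 and 38.6 CPM. The metallothioneins Mt1 and Mt2, which bind zinc, had means of 1311 and 766 CPM in vehicle, 1686 and 918 in H10, 2189 and 1333 in H90, 2017 and 1073 in M10, and 2775 and 1597 in M90.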
